A study of Mus musculus with 18 samples.

How the data were processed

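The measurements are RNA-seq libraries of beta cells sorted from mouse pancreatic islets. The mice lacked the insulin receptor in the liver (LIRKO) or were controls (Ctrl), and were on chow or on HFD, read here as high-fat diet. Per the labels, the islets were cultured overnight and dispersed, the cells were gated by light scatter and by their own fluorescence, and directional libraries were made from total RNA. The 18 libraries fall into 4 groups by genotype and diet: 6 Ctrl chow, 5 Ctrl HFD, 4 LIRKO chow and 3 LIRKO HFD. The labels do not say which libraries come from separate animals, and they give no sex, age, batch or pairing. The p-values below therefore measure the spread between these libraries, which may be technical in part. Replicate numbers follow the order of the deposited samples and carry no further meaning.

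The deposited table holds counts, the unnormalised whole numbers of reads per Ensembl gene, with 1 column per library. The authors list STAR, featureCounts and the mouse genome GRCm38. The versions, the annotation release and the strand setting are not given in the sources used here. Total counts ran from 19490235 to 51714775 reads per library, and the number of genes with at least 10 counts from 15884 to 18971. Of 53090 gene IDs, 52403 matched a symbol in GENCODE release M21, which is annotated on GRCm38, by ID without its version. The 687 others held at most 0.102% of the counts of any library. Coordinates are those of the same release.

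Genes were tested in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr on the groups, which left 19284. Libraries were scaled by TMM. A quasi-likelihood model (glmQLFit and glmQLFTest) with 1 coefficient per group was fitted to all 18 libraries, so that the 4 groups share 1 estimate of the spread. The square root of the common dispersion was 0.314. The 5 comparisons were LIRKO against Ctrl on chow, LIRKO against Ctrl on HFD, HFD against chow in Ctrl, HFD against chow in LIRKO, and the genotype by diet interaction, which is the genotype difference on HFD minus that on chow. All tests are two-sided, p-values were adjusted by Benjamini and Hochberg within each comparison, and a gene passed at an adjusted p under 0.05. Fold changes are on the log2 scale with their standard error (SE). Counts per 1e6 reads (CPM) use the TMM-scaled library sizes and are given with their standard deviation (SD) between libraries.

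Gene lists for beta cell identity and secretion, dedifferentiation, genes normally silenced in beta cells, cell cycle, stress responses, insulin and IGF signalling, lipid and energy metabolism, translation, lactogenic signalling, inflammation, senescence and cell isolation, and marker lists for the other cell types of the pancreas, were written before the data were examined, as were the comparisons, the tests, the rule for named genes and most of the alternatives. Of these, 33 lists had at least 5 tested members. A list of erythrocyte markers had fewer and was not tested. Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, adjusted over the 33 lists. The same test with the correlation estimated from the data, and fry, stand beside it. Camera compares a list with all other genes, while fry asks whether its members move on balance one way. Member counts are given over all genes tested and adjusted over the list alone. A score per library, the mean log2 CPM of the tested members with a prior count of 2, was compared between groups by a two-sided exact permutation test. With 3 against 4 libraries that test has 35 splits and cannot give a p under 0.0286.

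The rule for named genes took, in each of the 4 pairwise comparisons, the 10 largest rises and the 10 largest falls among genes past the threshold with a named symbol and a mean log2 CPM of at least 2. It added up to 4 members of each process list with the smallest p past the threshold, the 3 members of each marker list with the highest CPM, and 24 genes fixed in advance. For the interaction it took 5 genes in each direction, or the 3 smallest p-values where none passed. It gave 412 pairs of gene and comparison, of which 219 were chosen for the text, 3 of them not reported here. The 219 were chosen after the fold changes were seen and before the alternatives were run. Afterwards 10 that did not pass were taken out for a time because their sign changed, and were put back.

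The gene test was checked on counts simulated from the fitted dispersions with 200 changed genes per comparison. In LIRKO against Ctrl on chow it recovered 11.9% of 1.5-fold, 31.3% of 2-fold and 78.8% of 4-fold changes, with 4.71% of its calls false. For LIRKO against Ctrl on HFD these shares were 1.49%, 34.3%, 74.2% and 5.19%. For HFD against chow they were 17.9%, 47.8%, 77.3% and 5% in Ctrl, and 4.48%, 22.4%, 71.2% and 2.99% in LIRKO. The interaction test recovered 0%, 13.4% and 47.0%, with 4.76% false. Each simulated library was drawn on its own, so none was near-identical to another or stood apart. The false shares therefore need not hold in the real libraries, where 1 other grouping gave 6020 genes. A list raised 1.5-fold was called in all 5 comparisons, and 0 unchanged lists were. Each gene was drawn on its own, so the simulated lists hold no correlation between members. They cannot say how often camera calls unchanged lists in the real libraries, where other groupings gave a median of 10 to 15 called lists.

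The alternatives fixed in advance were RLE size factors, library sizes alone, scaling without Ins1, Ins2, Iapp and mitochondrial genes, no filter or a stricter filter (CPM of at least 1 in 6 libraries), DESeq2 1.42.0, limma voom with quality weights, fits of the compared groups alone, covariates (acinar score, alpha and delta scores, library size, 1 surrogate variable from sva 3.50.0), a minimum log2 change of 1, and leaving out each library in turn. Added after the data were seen were leaving out Ctrl HFD replicates 1 and 2, summing the counts of LIRKO chow replicates 1 and 2 and of 3 and 4, covariates for the endothelial score and for the protein-coding share of counts, the 2 other ways of summing the LIRKO chow libraries to 2, each pair of Ctrl HFD libraries left out, list scores with libraries left out, the estimated correlation and exact tests with the LIRKO chow pairs summed, and rerunning the correlations and list scores under the alternative fits. Correlations of fold changes run across genes, which are not independent replicates, so no p is given for them. For the pair of comparisons that shares the Ctrl chow libraries, 20 simulated data sets with unchanged groups and all 20 splits of these controls into 3 and 3 stand beside the observed value. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.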

Results

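Beta cell transcripts were counted in 18 libraries, 6 from Ctrl mice on chow, 5 from Ctrl mice on HFD, 4 from LIRKO mice on chow and 3 from LIRKO mice on HFD. Total counts per library were 24979993 to 43987306 in Ctrl chow, 19490235 to 35281010 in Ctrl HFD, 37138131 to 51714775 in LIRKO chow and 34790225 to 38795120 in LIRKO HFD. The insulin genes Ins1 and Ins2 together took 8.97% to 18.7% of the counts of a library. The Y-linked gene Ddx3y was at 68.2 to 166 CPM in the 18 libraries and Xist, the RNA of the inactive X chromosome, at 0.107 to 1.06 CPM.

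The libraries differed in ways that group alone did not give. The first principal component of the 500 most variable genes held 42.6% of their variance and set Ctrl HFD replicates 1 and 2 (49.9 and 47.8) apart from the other 3 Ctrl HFD libraries (−11.5 to −3.98). Those 2 libraries had the lowest total counts, the highest share of the nuclear RNA Malat1 (1.37% and 1.06%, against 0.0866% to 0.6003% elsewhere) and the lowest share of protein-coding counts (95.7% and 95.5%, against 97.1% to 98.8%). LIRKO chow replicates 1 and 2 were near-identical, and so were replicates 3 and 4. The spread of the log2 ratio between libraries (median absolute deviation over 13424 genes) was 0.109 and 0.121 in these pairs and at least 0.203 in every other pair from 1 group. All 4 were kept as the labels list them, and each lead count is also given with the pairs summed. Differences within the pairs exceeded counting noise, which does not show that the libraries come from separate animals or preparations. Endothelial marker scores split the same group, at −0.04 and 0.16 in replicates 1 and 2 and 3.40 and 3.22 in replicates 3 and 4.

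**Figure D1:**
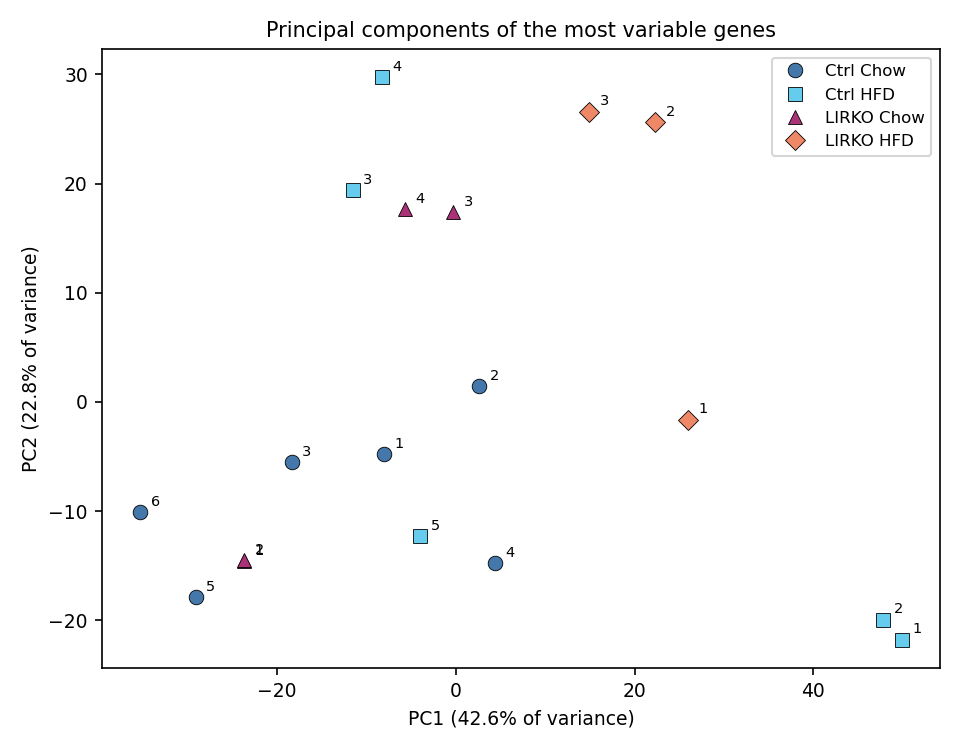
First and second principal components of log2 CPM of the 500 most variable genes, with the share of variance on each axis, 1 point per library and the replicate number beside it. Ctrl HFD replicates 1 and 2 lie at 49.9 and 47.8 on the first component, and LIRKO chow replicates 1 and 2 lie on top of each other at −23.7 and −23.6.

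The insulin receptor gene Insr (ENSMUSG00000005534, chromosome 8, 3122061 to 3279617 on GRCm38) is deleted in the liver of LIRKO mice, so its level in beta cells does not test the knockout. Insr stood at 52.7 ± 5.93 CPM (SD, n = 6) in Ctrl chow, 49.8 ± 14.1 (n = 5) in Ctrl HFD, 58.3 ± 2.46 (n = 4) in LIRKO chow and 53.6 ± 1.07 (n = 3) in LIRKO HFD. In the Ctrl HFD group, replicates 1 and 2 were at 33.4 and 35.8 CPM and the other 3 at 57.2 to 63.5. None of the 4 pairwise edgeR tests passed for Insr, with log2 changes of 0.15, 0.10, −0.08 and −0.12 whose sign depended on the setting, and adjusted p-values from 0.674 to 0.929. Ins1 and Ins2, near-identical paralogs whose reads can be assigned to either, did not pass in any pairwise comparison. Ins1 was at 41322 ± 8249 CPM and Ins2 at 119260 ± 23771 CPM in Ctrl chow.

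In chow-fed LIRKO mice the beta cell libraries held more transcripts of Mki67, of Aldh1a3 and of Etv5 than those of Ctrl mice, and fewer of Pdx1, a transcription factor that maintains beta cell identity. Lists of mitotic genes, of protein folding in the endoplasmic reticulum (ER) and of dedifferentiation were higher by camera, and 0 of these 3 passed with an estimated correlation (adjusted p = 0.346, 0.55 and 0.55). This comparison asks what beta cells express where the liver cannot respond to insulin. Aldh1a3, a retinaldehyde dehydrogenase used as a marker of dedifferentiated beta cells (ENSMUSG00000015134, chromosome 7, 66390890 to 66427517), rose 17.7-fold, from 4.92 ± 7.96 CPM (SD, n = 6) to 88.0 ± 8.41 (n = 4), with an adjusted p of 0.00106. Ctrl chow replicate 3 held 21.1 CPM of Aldh1a3 against 1.14 to 2.19 in the other 5, and without it the log2 change was 5.71 in place of 4.14. The proliferation marker Mki67 rose 4.07-fold, from 3.67 ± 1.74 to 14.9 ± 2.93 CPM (adjusted p = 0.00183), and every LIRKO chow library (12.1 to 17.9) was above every Ctrl chow library (2.05 to 6.04). Etv5, an ETS family transcription factor induced by growth factor signalling (ENSMUSG00000013089, chromosome 16, 22381309 to 22439719), rose from 6.39 ± 1.31 to 22.0 ± 2.37 CPM, with an adjusted p of 5.87e-06.

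In the comparison as a whole, 569 genes were higher and 424 lower in LIRKO chow out of 19284 tested, 993 in all. With LIRKO chow replicates 1 and 2 summed and replicates 3 and 4 summed, 193 genes passed, 144 higher and 49 lower, and all 193 were among the 993. Leaving out Ctrl HFD replicates 1 and 2, which belong to neither group but share the fit, gave 1765.

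The list of G2 and M phase genes rose: 12 of 33 members were higher and 0 lower, 31 when adjusted over the list alone, with a median log2 change of 1.202 (camera adjusted p = 3.02e-23, and adjusted p = 0.346 with an estimated correlation). Its score per library was higher in all 4 LIRKO chow libraries than in any of the 6 Ctrl chow libraries (exact permutation p = 0.00952, and 0.0357 with the pairs summed, the lowest that 28 splits can give). Besides Mki67, the kinetochore gene Ndc80 rose by 1.76 (log2), the mitotic kinase gene Cdk1 by 1.73, the DNA topoisomerase gene Top2a by 1.73 and the centromere motor gene Cenpe by 1.28. With the pairs summed, 1 of the 33 members passed and the median was 1.21. Of 30 S phase genes 1 was higher (camera adjusted p = 0.0652), and of 17 regulators of G1 phase 0 passed (camera adjusted p = 0.917, 0 by list alone). The G1 cyclin gene Ccnd2 had a log2 change of −0.20 and the cell cycle inhibitor gene Cdkn1a one of 0.43, and neither passed (adjusted p = 0.543 and 0.129).

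ER chaperone and folding genes rose as a list, with 5 of 34 higher and 0 lower, 11 when adjusted over the list alone (camera adjusted p = 3.75e-07, and adjusted p = 0.55 with an estimated correlation). The members that passed included Derl3, of the ER degradation machinery, at 40.3 ± 7.69 against 4.67 ± 1.42 CPM, Fkbp11, a prolyl isomerase, at a log2 change of 1.66, the chaperone cofactor Creld2 at 0.97 and the chaperone Hsp90b1 at 0.76. The main ER chaperone gene Hspa5 had a log2 change of 0.47 that did not pass (adjusted p = 0.217). Targets of ATF4, the transcription factor of the integrated stress response, rose with 5 of 30 higher and 0 lower, also 5 over the list alone (camera adjusted p = 5.52e-05, and adjusted p = 0.55 with an estimated correlation). Among them Stc2, a secreted glycoprotein, rose by 2.35, Ppp1r15a, a phosphatase subunit that restores translation, by 0.86, the mitochondrial serine enzyme Shmt2 by 0.54 and the mTOR inhibitor Ddit4 by 0.49, while Ddit3, a stress-induced factor, was at −0.23 (adjusted p = 0.611). Exact permutation p-values for the scores of these lists were 0.00952 and 0.00476. With the pairs summed 2 of 34 and 1 of 30 members passed, at medians of 0.34 and 0.25 in place of 0.34 and 0.24, and each exact p was 0.0357.

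Of 16 genes on the dedifferentiation and progenitor list, 6 were higher and 1 lower, 7 and 3 over the list alone (camera adjusted p = 0.0257, and adjusted p = 0.55 with an estimated correlation). Cck, a gut hormone expressed in beta cells of obese mice, rose from 0.0295 ± 0.0287 to 1.00 ± 0.266 CPM, and Npy, a neuropeptide of fetal beta cells, fell by 2.07. The beta cell identity and secretion list was lower, with 3 of 38 higher and 5 lower, 4 and 9 over the list alone (camera adjusted p = 0.0145, and adjusted p = 0.731 with an estimated correlation). With the pairs summed 0 of these 38 passed, at a median of −0.20 in place of −0.21 (exact permutation p = 0.107 in place of 0.0333), and 3 dedifferentiation genes were higher and 1 lower. Pdx1 (ENSMUSG00000029644) fell from 138 ± 25.4 to 73.7 ± 12.9 CPM (adjusted p = 0.00452), and with the pairs summed its log2 change stayed at −0.90 with an adjusted p of 0.092. The exocytosis gene Stx1a fell by 0.68. The granule proteins Chgb and Scg3 rose by 0.83 and 0.56. Not passing were the maturity factor Mafa at −1.16 (adjusted p = 0.167), the glucose transporter gene Slc2a2 at −0.99 (0.137), Ucn3, a peptide of mature beta cells, at −0.98 (0.119), Nkx6-1, a beta cell transcription factor, at −0.50 and the incretin receptor gene Glp1r at −0.35. Ins1 was at 0.24 and Ins2 at −0.02, a value whose sign depended on the setting.

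In insulin and IGF signalling, 2 of 31 genes were higher and 2 lower, 3 and 4 over the list alone (camera adjusted p = 0.492). The insulin receptor substrate gene Irs2 rose by 1.23, from 27.8 ± 8.86 to 65.3 ± 4.43 CPM, and the kinase gene Rps6kb1 by 0.44, while the growth factor gene Igf2 fell by 1.62 and Igfbp7, an IGF binding protein, by 0.75. The IGF1 receptor gene Igf1r had a log2 change of 0.14 (adjusted p = 0.729). Of 22 fatty acid synthesis genes 4 were higher and 1 lower (camera adjusted p = 0.972, median −0.15 and mean 0.04), with the glucose-induced arrestin Arrdc4 at 1.47, the lipogenic genes Thrsp at 1.53 and Dgat2 at 1.42, and the desaturase gene Scd1 at −1.49. The hypoxia list rose with 1 of 18 higher, 6 over the list alone (Mxi1, log2 change 0.67, camera adjusted p = 1.38e-05, and adjusted p = 0.731 with an estimated correlation). Oxidative phosphorylation and cytosolic ribosome genes were lower as lists, with 0 of 72 and 0 of 59 members passing and medians of −0.46 and −0.47 (camera adjusted p = 4.33e-10 and 3.75e-07, and adjusted p = 0.819 and 0.898 with an estimated correlation). Among 26 oxidative stress genes 2 were higher, the heme oxygenase gene Hmox1 by 1.84 and Gpx3, a secreted glutathione peroxidase, by 2.12, and 1 was lower, the metallothionein gene Mt1, which fell by 1.08 (camera adjusted p = 0.917).

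The largest rises among well expressed genes also took in C1qtnf1, a secreted C1q family protein, from 1.29 ± 1.25 to 30.0 ± 1.57 CPM (adjusted p = 2.27e-05), and the gluconeogenic isoenzyme gene Fbp2, from 3.65 ± 1.18 to 42.7 ± 3.28 CPM. Serpina7, a thyroxine carrier, rose from 29.1 ± 26.3 to 203 ± 61.6 CPM. The opioid precursor Pdyn rose by 2.66, the kinase gene Mapk4 by 2.52, Pappa2, a protease of IGF binding proteins, by 2.34, the activin subunit gene Inhba by 2.28 and the Rap exchange factor gene Rapgef5 by 2.24. Among the largest falls were Fam196a (−2.54), T2 (−2.26), the matrix proteins Reln (−2.26), Ltbp2 (−2.06), Emid1 (−1.87) and Col6a3 (−1.79), the lysosomal channel Mcoln3 (−1.96), the BMP target Id3 (−1.88), the potassium channel Kcnj12 (−1.78) and the mesothelin gene Msln (−1.78). Ctrl chow replicate 3 was far above the other 5 Ctrl chow libraries for Aldh1a3, C1qtnf1 and Rapgef5, replicate 2 for Stc2 and Serpina7 and replicate 1 for Hsp90b1, while replicate 1 was far below for Ltbp2.

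Pancreatic polypeptide (PP) cell markers were lower as a list, with 1 of 9 higher and 2 lower, 1 and 5 over the list alone (camera adjusted p = 0.0446, and adjusted p = 0.731 with an estimated correlation). The peptide hormone gene Pyy fell from 312 ± 197 to 91.9 ± 32.6 CPM, while Ppy had a log2 change of −2.01 that did not pass (adjusted p = 0.0804). Somatostatin (Sst) was at −1.01 and glucagon (Gcg) at −0.13, and neither passed (adjusted p = 0.179 and 0.96). The sign of Gcg changed with single libraries left out (−0.67 to 0.24). Of 14 alpha cell markers 4 were higher (camera adjusted p = 0.0652) and of 10 delta cell markers 1 (camera adjusted p = 0.611). Macrophage markers were lower as a list, with 0 of 20 higher and 1 lower (camera adjusted p = 0.000633, and adjusted p = 0.819 with an estimated correlation). Their score was low in LIRKO chow replicates 1 and 2 (1.69 and 1.63), while replicates 3 and 4 (3.16 and 3.08) lay within the Ctrl chow range (2.35 to 3.56). Endothelial markers had a median of 0.32 but a lower score and camera direction, with 0 of 17 passing (camera adjusted p = 0.595), and acinar markers a median of −0.14 but a higher score and camera direction, with 0 of 22 passing (camera adjusted p = 0.0652).

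Camera called 10 of the 33 lists in this comparison, fry 4, the exact tests 7 before and 0 after adjustment, and 0 lists passed with an estimated correlation. The naming rule took 62 genes that passed, of which 52 were chosen for the text. Of these 52, 24 kept their call under every alternative setting, among them Aldh1a3, Mki67, Etv5 and C1qtnf1. Leaving out LIRKO chow replicate 1, 3 or 4 gave 635, 431 and 444 genes.

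**Figure D2:**
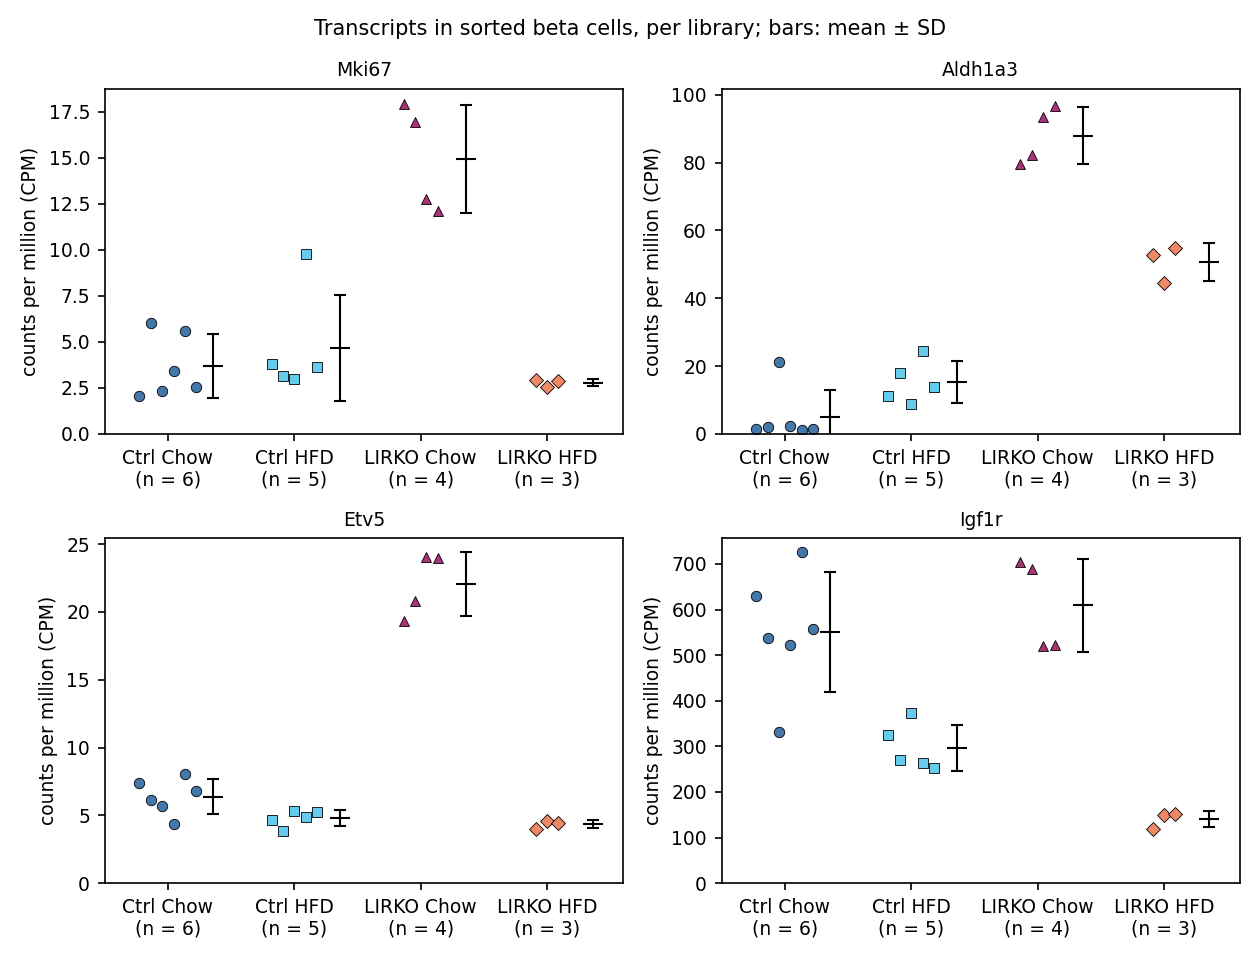
CPM (vertical axis, from 0) of Mki67, Aldh1a3, Etv5 and Igf1r in each group, 1 point per library, with bars for the mean and SD (n = 6, 5, 4 and 3). Mki67 averaged 14.9 CPM in LIRKO chow and 2.78 in LIRKO HFD, Etv5 22.0 and 4.35, and Igf1r 609 and 140, while Aldh1a3 averaged 88.0 and 50.7 CPM in the LIRKO groups and 4.92 and 15.2 in the Ctrl groups.

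On HFD, 61 genes were higher in LIRKO than in Ctrl mice and 37 lower, 98 in all. C1qtnf1 rose again in LIRKO, from 2.98 ± 1.23 CPM (SD, n = 5) to 20.5 ± 1.40 (n = 3), with an adjusted p of 0.0101, and the GDNF receptor gene Gfra1 rose from 3.48 ± 1.01 to 19.3 ± 3.03 CPM. Lpl, the lipoprotein lipase, fell 3.75-fold, from 184 ± 41.9 to 49.1 ± 5.26 CPM (adjusted p = 0.00382), and Igf1r fell from 297 ± 50.7 to 140 ± 17.8 CPM (adjusted p = 0.0272). Every LIRKO HFD library was below every Ctrl HFD library for both genes.

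Other rises on HFD were those of Cck, at a log2 change of 3.49, Fbp2 at 2.21, the bone morphogenetic protein Bmp3 at 2.02, Rapgef5 at 1.90, Stc2 at 1.84, the acetylcholinesterase gene Ache at 1.71, the phosphatase gene Ptprk at 1.66, Sh3bgrl2 at 1.60, the ubiquitin ligase gene Pdzrn3 at 1.49 and Chgb at 0.94. The water channel Aqp4 rose from 11.7 ± 2.93 to 39.8 ± 8.07 CPM (adjusted p = 0.00382). Msln fell from 23.5 ± 9.56 to 2.31 ± 1.52 CPM and Ltbp2 from 9.84 ± 3.02 to 1.72 ± 0.201 CPM, each with an adjusted p of 0.00382. Mcoln3 (−3.22), Kcnj12 (−2.77), Fam196a (−2.51), Npy (−2.31), T2 (−2.07), Tex15 (−1.84), the cadherin Celsr1 (−1.68), the granule transport protein Mlph (−1.56) and Igf2 (−1.34) were lower as well. Ctrl HFD replicate 4 was far below the other 4 Ctrl HFD libraries for Lpl, at 113 CPM against 189 to 215.

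The cell cycle genes that passed on chow did not pass on HFD, where Mki67 had a log2 change of −0.75 and Top2a one of −1.47 (adjusted p = 0.704 and 0.482). Ctrl HFD replicate 4 held 9.79 CPM of Mki67 against 2.96 to 3.77 in the other 4. Aldh1a3 was at 50.7 ± 5.54 against 15.2 ± 6.11 CPM, a log2 change of 1.73 that did not pass (adjusted p = 0.482), although the 3 LIRKO libraries were all above the 5 Ctrl libraries. Pdx1 (−0.41), Mafa (−1.53), Ccnd2 (−0.63), Irs2 (0.36), Ins1 (−0.22) and Ins2 (−0.11) did not pass either. Ins1 and Ins2 changed sign under some settings, among them without Ctrl HFD replicates 1 and 2 (0.224 and 0.213).

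Camera called 13 lists, 9 higher and 4 lower, of which 0 passed with an estimated correlation (adjusted p = 0.781 to 0.859), 0 by fry and 0 by the exact test, with 0 at an exact p under 0.05. Higher were cholesterol synthesis (0 of 23 members passing, median 0.25, adjusted p = 0.00014), hypoxia (0 of 18, median 0.75, 0.00014), ER chaperones (0 of 34, median 0.23, 0.000216), interferon response (0 of 30, median 0.61, 0.000216) and glycolysis (1 of 19, median 0.68, 0.000391). Alpha cell markers (1 of 14, 0.0334), endothelial markers (0 of 17, 0.043), genes normally silenced in beta cells (0 of 23, 0.0481) and immediate-early genes (0 of 25, 0.0481) followed. Lower were beta cell identity (1 of 38 higher, 0 lower, 0.00303), ribosome (0 of 59, 0.00365), G2 and M phase (0 of 33, 0.0416) and oxidative phosphorylation genes (0 of 72, 0.043). Of these 13 lists 3 kept call and direction without Ctrl HFD replicates 1 and 2 (beta cell identity, G2 and M phase and endothelial markers). The score differences went from 0.79 to 0.42 for hypoxia, 0.77 to 0.35 for interferon response, 0.74 to 0.43 for glycolysis, 0.31 to 0.15 for cholesterol synthesis, 0.24 to 0.12 for ER chaperones, 0.36 to 0.04 for alpha cell markers and 0.39 to 0.27 for silenced genes. They went up from 0.42 to 0.73 for endothelial markers. Without LIRKO HFD replicate 1 the cholesterol difference was 0.12, and without replicate 2 that of immediate-early genes was 0.10 in place of 0.28. The directions of the ribosome, oxidative phosphorylation and G2 and M phase lists turned when single libraries or Ctrl HFD replicates 1 and 2 were left out.

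Without Ctrl HFD replicates 1 and 2, 193 genes passed, 83 of them among the 98, and with the LIRKO chow pairs summed 54 did. The count was 10 without LIRKO HFD replicate 3, 15 without replicate 2, 42 and 56 without Ctrl HFD replicates 5 and 3, and 162 without Ctrl HFD replicate 4. It was 19 when the 2 groups were fitted alone and 37 with library size as a covariate, and of the 27 genes chosen in this way that passed 3 kept their call under every setting, among them Lpl.

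In Ctrl mice on HFD, marker lists of blood vessel and matrix cells were higher by camera, and lists of cholesterol synthesis, ER folding and beta cell identity were lower. With an estimated correlation 0 of these 5 lists passed (adjusted p = 0.37 to 0.482). Mafa, a transcription factor of mature beta cells (ENSMUSG00000047591, chromosome 15, 75745490 to 75748228), fell 3.65-fold, from 64.0 ± 28.0 CPM (SD, n = 6) to 17.4 ± 10.6 (n = 5), with an adjusted p of 0.0312. The desaturase genes Scd1 and Scd2 fell by 1.84 and 1.15 on the log2 scale. The endothelial coreceptor gene Eng rose from 6.18 ± 5.42 to 23.3 ± 9.92 CPM and the matrix protein Sparc from 11.03 ± 7.54 to 46.3 ± 19.999 CPM. The neuropeptide gene Npy fell 10.4-fold, from 4.80 ± 1.87 to 0.461 ± 0.0939 CPM (adjusted p = 0.000201). In all 1075 genes were higher and 839 lower, 1914 of 19284. With the LIRKO chow pairs summed, which belong to neither group but share the estimate of the spread, 114 passed. With the 2 groups fitted alone 1 did. When Ctrl HFD replicates 1 and 2, which stand apart, were left out, 34 genes passed, 25 higher and 9 lower, of which 30 were among the 1914.

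Cholesterol synthesis genes fell as a list: 10 of 23 were lower and 0 higher, 17 when adjusted over the list alone, with a median of −0.54 (camera adjusted p = 2.1e-08, adjusted p = 0.37 with an estimated correlation, exact permutation p = 0.00216, adjusted 0.0238). Idi1 fell by 1.34, the sterol carrier gene Stard4 by 0.98, and the sterol enzymes Msmo1 and Nsdhl by 0.86 and 0.66. Of 22 fatty acid synthesis genes 6 were lower and 2 higher, 8 and 3 over the list alone (camera adjusted p = 0.0611), with the elongase gene Elovl6 at −0.63 and the glucose-induced gene Txnip at 0.85. ER chaperone genes fell with 12 of 34 lower and 0 higher, 19 over the list alone (camera adjusted p = 1.06e-07, and adjusted p = 0.37 with an estimated correlation), among them Pdia6 by 0.74, Calr by 0.65, Sdf2l1 by 0.63 and Manf by 0.57, while Hspa5 was at −0.48 (adjusted p = 0.0965). ATF4 targets fell with 5 of 30 lower and 1 higher, 9 and 1 over the list alone (camera adjusted p = 0.000117, and adjusted p = 0.37 with an estimated correlation). Among them the serine enzymes Psph and Psat1 fell by 0.99 and 0.78 and the folate enzyme Mthfd2 by 0.53, and the stress protein Nupr1 rose by 1.08. Without Ctrl HFD replicates 1 and 2 the score differences went from −0.36 to −0.25 for ER chaperones and from −0.26 to −0.15 for ATF4 targets, and camera still called both lists (adjusted p = 1.35e-06 and 0.00307). Ctrl HFD replicate 4 lay within the Ctrl chow range in both scores.

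The beta cell identity list fell with 7 of 38 lower and 1 higher, 14 and 1 over the list alone (camera adjusted p = 0.000284, adjusted p = 0.37 with an estimated correlation, exact permutation p = 0.00216, adjusted 0.0238). With Mafa fell the granule tethering gene Sytl4 by 1.13, the glucose-6-phosphatase gene G6pc2 by 0.86, the prohormone convertase gene Pcsk2 by 0.64 and Pdx1 by 0.55, and Slc2a2 did not pass at −0.89 (adjusted p = 0.0818). Without Ctrl HFD replicates 1 and 2, 0 of the 17 identity and cholesterol genes that had fallen still passed in edgeR, all 17 remained lower, and their median log2 change went from −0.82 to −0.53. The 17 had been picked as lower with the remaining libraries included. All 17 were lower whichever pair of Ctrl HFD libraries was left out, so the shared sign adds little. The other 3 Ctrl HFD libraries lay below all 6 Ctrl chow libraries in the identity score (8.44 to 8.68 against 8.71 to 9.07) and in the cholesterol score (4.97 to 5.0952 against 5.28 to 5.68). Ins1 and Ins2 were at −0.27 and −0.29 and did not pass. Aldh1a3 was at 1.61 (adjusted p = 0.0771) and Mki67 at 0.35 (adjusted p = 0.459), a sign that turned without Ctrl HFD replicate 4. Igf1r fell from 551 ± 131 to 297 ± 50.7 CPM (adjusted p = 0.0181), a call lost without Ctrl HFD replicates 1 and 2.

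Endothelial markers rose as a list, with 4 of 17 higher, all 17 over the list alone, and a median of 1.69 (camera adjusted p = 2.1e-08, adjusted p = 0.482 with an estimated correlation, exact permutation p = 0.00866). The abundant endothelial receptor genes Kdr, Flt1 and Pecam1 had log2 changes of 1.44, 1.69 and 1.70 that did not pass (adjusted p = 0.12, 0.0866 and 0.0575). Kdr and Flt1 changed sign with the alpha and delta scores as covariates, and with the endothelial score, of whose list both are members. Stellate cell and fibroblast markers rose with 2 of 19 higher, 14 over the list alone, and a median of 2.05 (camera adjusted p = 4.31e-06, adjusted p = 0.482 with an estimated correlation, exact permutation p = 0.0216). Of 5 Schwann cell and neuron markers 1 was higher, 3 over the list alone (camera adjusted p = 0.0829, exact permutation p = 0.00216, adjusted 0.0238). Macrophage markers rose as a list with 0 of 20 passing (camera adjusted p = 0.00362, and adjusted p = 0.643 with an estimated correlation). Delta, PP and lymphocyte markers had 0 members passing of 10, 9 and 6 (camera adjusted p = 0.235, 0.805 and 0.35). Acinar markers had a median of −0.77 but a higher score and camera direction, with 0 of 22 passing (camera adjusted p = 0.35), the elastase gene Cela1 at −1.28 and the trypsin gene Prss2 at −0.81, whose signs changed under some settings. Gcg was at 1.01 (adjusted p = 0.399) and also changed sign.

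Among the largest rises were those of Igfbp3 at 2.42, the fatty acid binding protein gene Fabp4 at 2.33, the laminin gene Lama5 at 2.03 and the collagen genes Col15a1 at 1.91 and Col7a1 at 1.80. Beside them rose Cck at 3.87, Dapl1 at 2.17, the mitochondrial leucyl-tRNA synthetase gene Lars2 at 1.88, the cholesterol hydroxylase gene Cyp46a1 at 1.72, the growth factor gene Igf1 at 1.67 and Gpx3 at 1.31. Igfbp3 and Dapl1 changed sign under a covariate for alpha and delta scores and for protein-coding share respectively. Ctrl chow replicate 3 was far above the other 5 Ctrl chow libraries for Eng, Col15a1, Lama5, Kdr, Igf1 and Prss2, and replicate 4 for Col7a1. The largest falls after Npy were those of Epb41l4a (−2.26), Reln (−2.08), the potassium channel subunit Kcnf1 (−1.59), Mcoln3 (−1.56), Fam196a (−1.4996), Fmo1 (−1.44), Mlph (−1.44), the monoamine oxidase gene Maob (−1.35) and the adhesion gene Nrcam (−1.28).

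Immediate-early genes, which also respond to cell isolation, rose with 3 of 25 higher, 5 and 1 lower over the list alone (Egr2 1.18, Nr4a1 1.15 and Ier2 0.87, camera adjusted p = 0.0048, and adjusted p = 0.643 with an estimated correlation). Oxidative phosphorylation genes fell with 6 of 72 lower and a median of −0.17 (camera adjusted p = 8.55e-05, and adjusted p = 0.697 with an estimated correlation), and scaling by library size alone shifted all genes by 0.177. Their score difference of −0.24 was −0.50 without Ctrl HFD replicates 1 and 2 (camera adjusted p = 9.07e-20) and −0.13 without replicate 4. Mitochondrially encoded genes (0 of 7, median −0.56, camera adjusted p = 0.0219), glycolysis genes (1 of 19 lower, 0.0121) and oxidative stress genes (3 of 26 lower, 1 higher, 0.00552) were lower as lists, and genes normally silenced in beta cells were higher (1 of 23, 0.0247). With an estimated correlation these 4 had adjusted p-values of 0.643, 0.643, 0.482 and 0.643. The score difference of the mitochondrially encoded genes went from −0.68 to −0.29 without Ctrl HFD replicate 4, which was at 9.08 against 10.6 to 11.6 in the other 4, and to −1.0959 without replicates 1 and 2 (camera adjusted p = 7.5e-06). That of the glycolysis genes went from −0.40 to −0.10 without Ctrl HFD replicates 1 and 2, and camera no longer called the list (adjusted p = 0.24).

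Camera called 13 lists, fry 8, the exact tests 9 before and 3 after adjustment, and 0 passed with an estimated correlation. Means of some library measures differed between the diets in the controls, and none passed after adjustment. Malat1 held 0.679% of counts on HFD and 0.201% on chow, rRNA genes 0.437% and 0.118% and protein-coding genes 96.9% and 98.3%. Their exact permutation p-values were 0.0108, 0.0325 and 0.00866 (adjusted p = 0.140, 0.143 and 0.140). Ctrl HFD replicates 1 and 2 weighed in these means, with Malat1 at 1.37% and 1.06% against 0.276% to 0.415% in replicates 3, 4 and 5. The rRNA share was 0.457% and 1.09% in replicates 1 and 2, and 0.0690%, 0.180% and 0.393% in replicates 3, 4 and 5. Scaling by library size gave 2033 genes higher and 162 lower in place of 1075 and 839. The count fell to 1 when the 2 groups were fitted alone, 1 with the endothelial score and 1 with the alpha and delta scores as covariates, 2 with library size and 2 with the protein-coding share. Leaving out 1 library gave between 69 (without Ctrl chow replicate 6) and 3877 genes (without Ctrl chow replicate 4), and of the 48 chosen genes that passed, Npy alone kept its call under every setting.

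**Figure D3:**
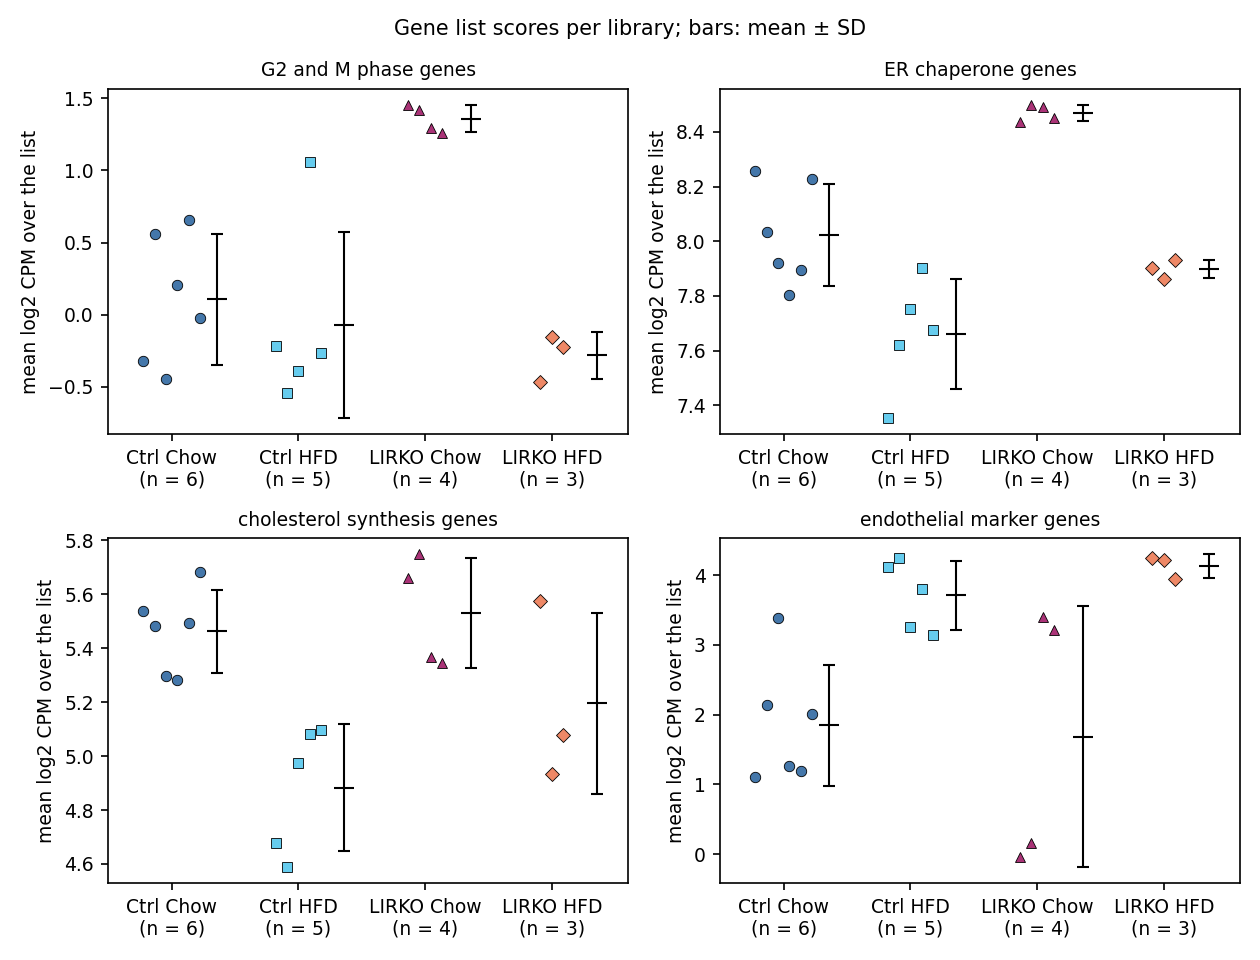
Mean log2 CPM over the members of 4 gene lists (vertical axes, which do not start at 0) in each group, 1 point per library, with bars for the mean and SD (n = 6, 5, 4 and 3). G2 and M phase scores averaged 1.36 in LIRKO chow and −0.28 in LIRKO HFD, and endothelial marker scores averaged 3.71 in Ctrl HFD and 4.13 in LIRKO HFD against 1.85 in Ctrl chow.

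In LIRKO mice, HFD went with fewer transcripts of Igf1r, and the list of ATF4 stress response genes was lower (adjusted p = 0.0447 with an estimated correlation, and 0.0891 with the LIRKO chow pairs summed). By camera, mitotic genes were lower and macrophage markers higher as lists, and neither list passed with an estimated correlation (adjusted p = 0.144 and 0.219). Igf1r (ENSMUSG00000005533, chromosome 7, 67952827 to 68233668) fell 4.34-fold, from 609 ± 101 CPM (SD, n = 4) to 140 ± 17.8 (n = 3), with an adjusted p of 0.000365. Etv5 fell from 22.0 ± 2.37 to 4.35 ± 0.306 CPM (adjusted p = 1.48e-05), and Star, which carries cholesterol into mitochondria, from 130 ± 16.4 to 14.3 ± 0.627 CPM (adjusted p = 0.00303). Mki67 fell from 14.9 ± 2.93 to 2.78 ± 0.198 CPM (adjusted p = 0.0127). In each of these 4 genes every LIRKO HFD library was below every LIRKO chow library. A total of 204 genes were higher and 188 lower, 392 in all, and 7 passed with the LIRKO chow pairs summed.

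G2 and M phase genes fell with 13 of 33 lower and 0 higher, 24 over the list alone, and a median of −1.69 (camera adjusted p = 4.95e-23, adjusted p = 0.144 with an estimated correlation, exact permutation p = 0.0286). With the LIRKO chow pairs summed the median was −1.7018, 0 of 33 members passed, and the exact p was 0.1, the lowest that 10 splits can give. Top2a fell by 3.40, Cdk1 by 2.67 and Cenpe by 1.69, S phase genes were lower with 0 of 30 passing (camera adjusted p = 0.0149, and adjusted p = 0.37 with an estimated correlation), and Ccnd2 was at −0.65 (adjusted p = 0.0817). ATF4 targets fell with 6 of 30 lower, 21 over the list alone, and passed both forms of camera (adjusted p = 5.84e-15, and adjusted p = 0.0447 with an estimated correlation). With the pairs summed the estimated correlation gave an adjusted p of 0.0891 at a median of −0.53 in place of −0.52. Psph fell by 1.14, Psat1 by 0.94, the pseudokinase gene Trib3 by 0.87 and Chac1, a glutathione-degrading enzyme, by 0.62. ER chaperone genes fell with 2 of 34 lower, 15 over the list alone (camera adjusted p = 1.85e-13, and adjusted p = 0.144 with an estimated correlation), Sdf2l1 by 0.98 and Creld2 by 0.93, while Hspa5 was at −0.69 (adjusted p = 0.164). Beta cell identity genes were lower with 3 of 38 passing, 7 lower and 1 higher over the list alone (Mafa −2.24, Sytl4 −1.33 and Scg3 −0.58, camera adjusted p = 0.00131, and adjusted p = 0.241 with an estimated correlation). Cholesterol synthesis genes were lower with 0 of 23 passing (median −0.27, camera adjusted p = 0.000574, and adjusted p = 0.483 with an estimated correlation). Scaling by library size alone shifted all genes by 0.222, close to the last median and to that of the identity list (−0.22).

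Macrophage markers rose with 5 of 20 higher, 17 over the list alone, and a median of 1.495 (camera adjusted p = 4.73e-12, and adjusted p = 0.219 with an estimated correlation). The myeloid genes Clec7a (2.14), Acp5 (2.11), Tyrobp (2.03), Vsir (1.99), Cyba (1.94) and Coro1a (1.85) rose. Endothelial markers rose with 1 of 17 higher, 10 over the list alone (camera adjusted p = 8.63e-14, and adjusted p = 0.229 with an estimated correlation), and stellate and lymphocyte markers with 0 of 19 and 0 of 6, 8 and 3 over the list alone (camera adjusted p = 1.92e-10 and 0.0149, and adjusted p = 0.21 and 0.184 with an estimated correlation). Exact permutation p-values for the endothelial, macrophage and stellate scores were 0.0857, with LIRKO chow replicates 3 and 4 between replicates 1 and 2 and the HFD libraries for the endothelial score. The macrophage score was 1.69 and 1.63 in LIRKO chow replicates 1 and 2, 3.16 and 3.08 in replicates 3 and 4 and 3.78 to 4.0955 on HFD. Genes normally silenced in beta cells were higher with 1 of 23 passing (camera adjusted p = 0.00138, and adjusted p = 0.44 with an estimated correlation), as were immediate-early genes with 2 of 25 (Egr3 2.78 and Egr2 2.50, camera adjusted p = 0.0186, and adjusted p = 0.688 with an estimated correlation).

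Other rises were those of Id3 (2.35), the retinaldehyde reductase Dhrs3 (2.07), the activity-induced gene Arc (1.99), the transcription factor Mef2c (1.92) and the cytokine-induced inhibitor Cish (0.91). Other falls were those of Npy (−3.61), Epb41l4a (−3.10), Mcoln3 (−2.83), Ipcef1 (−2.65), Pdyn (−2.52), Nrcam (−2.51), Msln (−2.32) and the kinase gene Plk3 (−1.43). Aldh1a3 was at −0.80 (adjusted p = 0.595), Ins1 at −0.73 (adjusted p = 0.261) and Ins2 at −0.38 (adjusted p = 0.523), which did not pass.

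Camera called 12 lists, fry 10, the exact tests 6 before and 0 after adjustment, and the ATF4 list alone passed with an estimated correlation, and 0 lists did with the pairs summed. In each of the 12 lists 0 members passed with the pairs summed. The exact tests take the 4 LIRKO chow libraries as independent. Scaling by library size gave 504 genes higher and 86 lower in place of 204 and 188. The count was 55 without LIRKO chow replicate 1 or 2, 100, 56 and 67 without LIRKO HFD replicates 1, 2 and 3, and 4 with the endothelial score as a covariate. Library measures moved with this comparison as well. The share of Malat1 was 0.554% on HFD and 0.297% on chow, that of rRNA genes 0.175% and 0.0779% and that of protein-coding counts 97.5% and 98.2%, without overlap (exact permutation p = 0.0286 and adjusted p = 0.140 for each). With the protein-coding share as a covariate 433 genes passed, Igf1r among them at −2.11. The count was 1191 without Ctrl HFD replicates 1 and 2, and of the 38 chosen genes that passed 3 kept their call under every setting, Npy, Etv5 and Igf1r.

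The interaction asks whether the genotype difference itself differs between diets. Etv5 was the single gene of 19284 to pass, with a log2 difference of −1.93 ± 0.24 (SE) and an adjusted p of 0.0051. Its level was 22.0 CPM in LIRKO chow and 4.35 to 6.39 CPM in the other 3 groups. The unadjusted p was under 0.05 in 1065 genes, DESeq2 called 42 genes and limma 43, and the call of Etv5 was lost with the LIRKO chow pairs summed (0 genes, Etv5 at −1.93 with an adjusted p of 0.113) and without LIRKO HFD replicate 1 (0 genes). Without Ctrl HFD replicates 1 and 2, 8 genes passed, Etv5 among them. Mki67 (−2.77, adjusted p = 0.136), Top2a (−3.20, adjusted p = 0.373), Igf1r (−1.23, adjusted p = 0.315) and Aldh1a3 (−2.41, adjusted p = 0.833) did not pass, so their genotype differences are not shown to differ between the diets. A positive value means that LIRKO minus Ctrl was higher on HFD than on chow, whatever its sign on each diet. Among positive values the smallest p-values were those of Cntfr, a cytokine receptor (1.02, adjusted p = 0.126), Prkg2, a cGMP-dependent kinase (1.35, adjusted p = 0.126), and Zfp703 (1.22, adjusted p = 0.136). G2 and M phase genes were lower as a list with 0 of 33 passing, 22 over the list alone, and a median of −1.44 (camera adjusted p = 1.19e-29, adjusted p = 0.151 with an estimated correlation, fry adjusted p = 0.0552). ATF4 targets were lower with 0 of 30 passing (camera adjusted p = 2.09e-06, and adjusted p = 0.386 with an estimated correlation). Camera called 10 lists for the interaction, and 0 were called with an estimated correlation and 0 by fry.

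Fold changes were also set side by side across genes. The genotype difference on chow and that on HFD, which share no library, had a Pearson correlation of 0.452 (Spearman 0.385) over 19284 genes. Of 1028 genes past the threshold in either, 88.9% had the same sign, and 39 genes were higher and 24 lower in both. The product of the 2 counts over all genes gives 1.80 and 0.814. The diet difference in Ctrl and that in LIRKO, also without a shared library, had a Pearson correlation of 0.658 (Spearman 0.662). Of 2185 genes past the threshold in either 93.0% had the same sign, 57 were higher and 63 lower in both against 11.4 and 8.18 from such products, and 1 was opposite. These products take genes as independent, which they are not, so an excess over them does not by itself show a shared response. The Pearson correlations were 0.239 and 0.351 without Ctrl HFD replicates 1 and 2.

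The genotype difference on chow and the diet difference in Ctrl share the 6 Ctrl chow libraries. Their Pearson correlation was 0.241 (Spearman 0.208), below the mean of 0.421 in 20 simulated data sets with unchanged groups. The covariance was 0.0980 against 0.0654 in the simulations, a difference of 0.0326. Among genes with a mean log2 CPM of at least 3 it was 0.0173 against 0.0183 (0.0170 to 0.0192 over the simulations), so no excess was seen there. With the 6 controls split 3 and 3 the mean correlation was 0.110, from −0.163 to 0.442. In both comparisons 129 genes were higher and 80 lower, against 31.7 and 18.4 from the product of the 2 counts over all genes, and 6 had opposite signs. Because of the shared controls those overlaps are not independent evidence of a common response.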

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

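The tests of a lower beta cell share, of the summed pairs, of the 17 lower genes and their list scores, of splits with the pairs summed and of the near-identical pairs were chosen after the result was seen, and the others were set before their own result was computed. Those of the summed pairs and of the 17 genes had first been set before, without controls of the same size. Their values of 1 and 0 then met what the explanations needed, a reading withdrawn once the controls were run. For the 17 genes the new rule asked most calls of every other pair left out, also of pairs that held Ctrl HFD replicate 1 or 2. Pairs that held neither kept 15 to 17, so a smaller sample alone does not account for those lost calls.

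The higher G2 and M phase list in LIRKO chow was weighed first. Were dividing endothelial, macrophage or lymphocyte cells the source, the rise was predicted to be lost with their 3 marker scores as covariates. The median log2 change of the members instead went from 1.202 to 1.51 with 12 still past the threshold. The 3 scores averaged lower in LIRKO chow than in Ctrl chow (differences −0.16, −0.67 and −0.39), so adjusting for them was unlikely to remove the rise. They show no larger mean amount of these cells, but do not measure the share of them that divides. With genes of very high counts left out of the scaling, the median was 1.19 with 11 members past the threshold. That setting moved the median gene of the comparison by −0.00883, so it could hardly change the list. A shift this small argues against such scaling as the source. With the LIRKO chow pairs summed 1 member passed in place of 12, at a median of 1.21 and a median SE of 0.468 in place of 0.361, but the 2 other ways of summing 4 libraries to 2 also left 1 member each, so the lost calls do not say whether the 4 libraries are independent. More mitosis in beta cells where the liver lacks the insulin receptor stays open, and so does a larger dividing share among other cells. The number of independent samples behind the rise stays open as well.

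The second pattern was HFD in controls, with higher endothelial and stellate markers and fewer beta identity and cholesterol transcripts. A lower share of beta cells with all other cells raised alike is argued against, since the endothelial score difference exceeded the delta score difference by 2.26 (SE 0.6253). That gap was the largest of those to the acinar, delta and PP scores. A lower share through more endothelial and stellate cells would not raise all markers alike, and it was not tested. The endothelial difference was 1.87 with all libraries and 1.56 (exact permutation p = 0.0476) without Ctrl HFD replicates 1 and 2, which argues against these 2 libraries as its source. Of the 17 beta identity and cholesterol genes that had fallen, 0 stayed past the threshold without these 2 libraries. Each pair of libraries left out that held 1 of the 2 kept 0 or 1, and each pair that held neither kept 15 to 17. All 17 were lower whichever pair was left out, which is close to given for genes picked as lower. The 2 libraries as the whole source of the lower levels are argued against by the other 3, with score differences from chow of −0.30 for identity and −0.41 for cholesterol synthesis (SE 0.0901 and 0.0730, exact permutation p = 0.0119 for each), so an effect of diet stays open beside their share in the calls.

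The third pattern was the near-identity of LIRKO chow replicates 1 and 2 and of replicates 3 and 4. Whether each pair is 1 cell preparation made into 2 libraries stays open. The median absolute log2 ratio of other-cell markers was at most 0.194 within the pairs and at least 0.242 in other pairs from 1 group, but the pairs were picked for small ratios over all genes. As a multiple of the spread over all genes it was 0.999 and 1.601, within the 0.641 to 4.95 of the other pairs. That 1 library was entered 2 times is argued against by a median chi-square 2.83 and 3.41 times that of counting noise. No biological explanation was tested.

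Regrouping the libraries asks whether chance can be excluded for a count of genes. It can for LIRKO chow against Ctrl chow, where 1 of 100 splits, the real one with 993 genes, gave as many and the highest other gave 260, and for LIRKO HFD against LIRKO chow, where 1 of 35 did (392 genes, highest other 0), if the 4 LIRKO chow libraries are independent. With the pairs summed it can for LIRKO chow against Ctrl chow, where 1 of 28 splits gave as many (193 genes, highest other 24), and for LIRKO HFD against LIRKO chow the 10 splits are too few for a share under 0.05 (7 genes, highest other 0). For the interaction 3 of 100 regroupings gave at least the 1 gene seen, a share under 0.05, if the 4 LIRKO chow libraries are independent. These regroupings shuffled genotype within each diet, which also breaks up the genotype difference common to both diets. They therefore cannot say whether chance explains the interaction count. The highest other regrouping gave 2279 genes and the next 9, and the reason was not tested. With the pairs summed 0 genes passed, which leaves no count to regroup. Chance is not excluded for LIRKO HFD against Ctrl HFD, where 6 of 56 splits gave at least 98 genes, nor for Ctrl HFD against Ctrl chow, where 5 of 100 gave at least 1914. Their highest other splits gave 6020 and 4903, more than the real counts, and the first, which sets Ctrl HFD replicates 1 and 2 with LIRKO HFD replicate 1 against the rest, points to sample structure. Without Ctrl HFD replicates 1 and 2, 3 of 84 splits of the controls gave at least 34 genes, a share under 0.05. These 2 libraries were left out after the data were seen, and with them chance was not excluded. The highest other split, Ctrl chow replicates 1, 2 and 4 against the rest, gave 2692 genes and the next 1709. The share therefore does not by itself exclude chance for this count.

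For counts of lists chance is not excluded in any comparison. As many lists came from 68 of 100 splits for LIRKO chow against Ctrl chow (10 lists, highest other 22), 20 of 56 for LIRKO HFD against Ctrl HFD (13, highest other 20) and 35 of 100 for Ctrl HFD against Ctrl chow (13, highest other 21). For LIRKO HFD against LIRKO chow it was 23 of 35 (12, highest other 24) and for the interaction 52 of 100 (10, highest other 19).

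Single libraries that stood apart within a group were sought with the ratio of gap to range, which by chance marks about 1 group in 20, and 30 of 558 groups were marked. In Ctrl HFD, replicate 4 stood apart for the G2 and M phase score (0.796), Mki67 (0.881), Top2a (0.857), Cdk1 (0.932), Arrdc4 (0.719) and Lpl (0.744). Replicate 2 did for Thrsp (0.851), and replicate 5 for Igf1 (0.775), Tyrobp (0.801) and Plk3 (0.712). In Ctrl chow, replicate 3 stood apart for Aldh1a3 (0.947), C1qtnf1 (0.779), Rapgef5 (0.658), Gfra1 (0.631), Pdzrn3 (0.752), Igf1 (0.634), Eng (0.797), Col15a1 (0.684), Lama5 (0.874), Kdr (0.770) and Prss2 (0.713). Replicate 1 did for Hsp90b1 (0.631) and Ltbp2 (0.799), replicate 2 for Stc2 (0.722) and Serpina7 (0.685), replicate 4 for Col7a1 (0.626) and replicate 6 for Chac1 (0.795). In LIRKO chow, replicate 2 stood apart for Pcsk2 (0.855) and Cyp46a1 (0.872), and replicate 1 for Nr4a1 (0.869).

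For the interaction Etv5 passed (edgeR adjusted p = 0.0051), a call lost with the LIRKO chow pairs summed and without LIRKO HFD replicate 1. Lists that camera called lower were G2 and M phase genes (adjusted p = 1.19e-29), ATF4 targets (2.09e-06) and ER chaperones (0.0315). Called higher were oxidative phosphorylation (6.77e-06), macrophage markers (3.52e-07), interferon response (0.00181), cholesterol synthesis (0.0158), ribosome (0.0158), PP cell markers (0.0158) and endothelial markers (0.0254, with a median of −0.01). The ribosome list turned lower without LIRKO HFD replicate 1 (camera adjusted p = 0.876). With an estimated correlation 0 of these 10 lists passed, and 0 did by fry, so a difference between diets is not shown for them.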

How the results depend on the processing

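The alternatives added after the fold changes were seen were those without Ctrl HFD replicates 1 and 2, with the LIRKO chow pairs summed, and with the endothelial score or the protein-coding share as a covariate. Later still came the 2 other ways of summing the LIRKO chow libraries to 2 (232 genes each against Ctrl chow) and each pair of Ctrl HFD libraries left out (3 to 6641 genes against Ctrl chow). No paired analysis was possible because the replicate numbers follow the order of the records and do not link animals. Where a value moved and no construction explains it, the cause was not tested.

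LIRKO chow against Ctrl chow gave 993 genes in edgeR, 1649 in DESeq2 and 3518 in limma. It gave 1653 with the 2 groups alone, 2463 with 1 surrogate variable, 2221 with the protein-coding share and 541 with a log2 change of at least 1 required. It was 1765 without Ctrl HFD replicates 1 and 2, and 193 with the pairs summed. Single libraries left out gave 431 to 919, with 635, 431 and 444 without LIRKO chow replicates 1, 3 and 4.

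LIRKO HFD against Ctrl HFD gave 98 genes in edgeR, 316 in DESeq2 and 924 in limma, 19 with the 2 groups alone, 323 with 1 surrogate variable, 37 with library size and 236 with the protein-coding share. It was 193 without Ctrl HFD replicates 1 and 2, and 54 with the LIRKO chow pairs summed. Single libraries left out gave 10 (LIRKO HFD replicate 3) to 162 (Ctrl HFD replicate 4), with 56 and 42 without Ctrl HFD replicates 3 and 5 and 15 without LIRKO HFD replicate 2.

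Ctrl HFD against Ctrl chow gave 1914 genes in edgeR, 3959 in DESeq2 and 73 in limma. It gave 457 without a filter, 1 with the 2 groups alone, 1 with the alpha and delta scores, 353 with 1 surrogate variable, 2 with library size, 1 with the endothelial score, 2 with the protein-coding share and 793 with a log2 change of at least 1 required. It was 34 without Ctrl HFD replicates 1 and 2, and 114 with the LIRKO chow pairs summed. Single libraries left out gave 69 (Ctrl chow replicate 6) to 3877 (Ctrl chow replicate 4). Without Ctrl chow replicates 1, 2 and 5 it was 97, 159 and 1271, and without Ctrl HFD replicates 1, 2, 3 and 5 it was 75, 97, 3826 and 3043. Scaling by library size gave 2033 higher and 162 lower, a median shift of 0.177.

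LIRKO HFD against LIRKO chow gave 392 genes in edgeR, 1059 in DESeq2 and 6104 in limma. It gave 590 with scaling by library size (504 higher and 86 lower, a median shift of 0.222), 250 without a filter, 3403 with the 2 groups alone, 6 with the alpha and delta scores, 786 with 1 surrogate variable, 217 with library size as a covariate and 4 with the endothelial score. It was 1191 without Ctrl HFD replicates 1 and 2, and 7 with the pairs summed. Single libraries left out gave 55 (LIRKO chow replicate 1 or 2) to 341, with 100, 56 and 67 without LIRKO HFD replicates 1, 2 and 3.

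The interaction gave 1 gene in edgeR, 42 in DESeq2 and 43 in limma, with 1065 genes at an unadjusted p under 0.05. It gave 5 with the alpha and delta scores, 23 with 1 surrogate variable, 8 with the protein-coding share, 8 without Ctrl HFD replicates 1 and 2, and 0 with the pairs summed. Single libraries left out gave 0 (LIRKO HFD replicate 1) to 3 (Ctrl chow replicate 3), with 2 without Ctrl chow replicate 5 and 2 without Ctrl HFD replicate 3.

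With an estimated correlation, camera called 0 lists in each comparison except LIRKO HFD against LIRKO chow, where it called 1. Fry called 4 in LIRKO chow against Ctrl chow, 0 in LIRKO HFD against Ctrl HFD, 8 in Ctrl HFD against Ctrl chow and 0 for the interaction. For LIRKO HFD against Ctrl HFD, camera called 5 lists without Ctrl HFD replicates 1 and 2 and 7 with the endothelial score in place of 13, and 6 to 13 with single libraries left out (6 without LIRKO HFD replicate 2, 8 without Ctrl HFD replicate 5). For Ctrl HFD against Ctrl chow it called 8 with the endothelial score in place of 13. Of 132 exact tests of list scores 22 had p under 0.05, 21 with a prior count of 0.5 and 32 with medians.

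Some lists turned direction. In LIRKO HFD against Ctrl HFD the ribosome list was higher without Ctrl HFD replicates 1 and 2 (camera adjusted p = 1.22e-06) and with the protein-coding share (0.512). With single libraries left out its p ran from 5.56e-09 to 0.947, turned without Ctrl HFD replicate 2 (0.947) and LIRKO HFD replicate 3 (0.806). The oxidative phosphorylation list turned without Ctrl HFD replicates 1 and 2 (0.0935) and without LIRKO HFD replicate 3 (0.333), in a range of 4.71e-09 to 0.892. The G2 and M phase list turned without Ctrl HFD replicate 4, in a range of 0.00425 to 0.988. For the interaction the ribosome list turned without LIRKO HFD replicate 1, in a range of 9.65e-08 to 0.876. With the endothelial score as a covariate the endothelial list turned, by construction, in LIRKO HFD against Ctrl HFD (0.505), Ctrl HFD against Ctrl chow (0.807), LIRKO HFD against LIRKO chow (0.597) and the interaction (0.928).

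The correlation of genotype differences was 0.452, against 0.132 without a filter and 0.239 without Ctrl HFD replicates 1 and 2 (jackknife SD 0.176). That of diet differences was 0.658, against 0.256 without a filter, 0.524 in limma, 0.492 with the alpha and delta scores, 0.547 with 1 surrogate variable, 0.539 with library size, 0.351 without Ctrl HFD replicates 1 and 2, 0.472 with the endothelial score and 0.466 with the protein-coding share (jackknife SD 0.105). The correlation that shares controls was 0.241 (jackknife SD 0.254).

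Ins2 in LIRKO chow against Ctrl chow was −0.02 and turned to 0.014 without a filter, 0.0012 with a strict filter, 0.016 in limma, 0.0047 with the 2 groups alone, 0.046 with the alpha and delta scores, 0.043 with 1 surrogate variable, 0.096 with library size and 0.018 without Ctrl HFD replicates 1 and 2, and ran from −0.10 to 0.066 with single libraries left out. Insr there turned to −0.053 with library size, and Gcg ran from −0.67 to 0.24 with single libraries left out.

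In LIRKO HFD against Ctrl HFD, Ins1 turned to 0.092 with library size, 0.224 without Ctrl HFD replicates 1 and 2 and 0.035 with the protein-coding share. Ins2 turned to 0.0019 with the alpha and delta scores, 0.044 with 1 surrogate variable, 0.078 with library size, 0.213 without Ctrl HFD replicates 1 and 2 and 0.055 with the protein-coding share, and ran from −0.40 to 0.077 with single libraries left out. Insr turned to −0.104 in limma, −0.139 with library size, −0.161 without Ctrl HFD replicates 1 and 2 and −0.0126 with the protein-coding share, and ran from −0.0074 to 0.207.

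In LIRKO HFD against LIRKO chow, Insr turned to 0.100 with scaling by library size, 0.054 with the alpha and delta scores, 0.092 with 1 surrogate variable, 0.050 with library size as a covariate, 0.00023 with the endothelial score and 0.111 with the protein-coding share.

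In Ctrl HFD against Ctrl chow, Insr turned to 0.104 with scaling by library size, 0.0999 in limma, 0.076 with the alpha and delta scores, 0.139 with 1 surrogate variable, 0.136 with library size, 0.228 without Ctrl HFD replicates 1 and 2, 0.0068 with the endothelial score and 0.298 with the protein-coding share, and ran from −0.18 to 0.035. Igfbp3 turned to −0.174 with the alpha and delta scores and Dapl1 to −0.191 with the protein-coding share, the 2 genes of 205 called by rule that turned, while 94 of the 207 not called did. With the alpha and delta scores and with the endothelial score, Kdr turned to −0.107 and −0.296, Flt1 to −0.040 and −0.223 and Gcg to −0.858 and −0.408. Cela1 turned to 0.682 with the alpha and delta scores. Prss2 turned to 1.07 in limma, 0.196 with the acinar score and 1.17 with the alpha and delta scores, and ran from −1.30 to 0.503. Mki67 ran from −0.119 (without Ctrl HFD replicate 4) to 0.550.

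Of 219 gene and comparison pairs chosen for the text 166 were called, and 102 were with the groups of the comparison alone, 78 with the alpha and delta scores, 90 with library size, 56 with the pairs summed and 80 with the endothelial score.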

Other observations

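Other gene lists did not pass camera, which does not show that they were level. In LIRKO chow against Ctrl chow, fatty acid oxidation genes had 2 of 32 higher and a median log2 change of 0.07 (camera adjusted p = 0.753), senescence genes 1 of 19 higher (0.917), lactogenic and serotonin genes 1 of 15 higher (0.917), genes normally silenced in beta cells 1 of 23 higher (0.818), immediate-early genes 1 of 25 higher (0.11) and glycolysis genes 1 of 19 lower with a median of 0.51 (0.0579). The cholesterol synthesis list, which fell on HFD in controls, had 0 of 23 passing and a median of 0.03 (0.595). Interferon response genes had 0 of 30 passing (0.972), and NF-kB inflammation genes 0 of 21, with a median of −0.18 against a higher camera direction (0.917). Ductal markers had 1 of 15 higher (0.595), stellate markers 1 of 19 lower (0.526), and lymphocyte, Schwann cell and mitochondrially encoded genes 0 of 6, 0 of 5 and 0 of 7 passing (0.44, 0.917 and 0.601), with a median of −0.73 for lymphocyte markers.

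On HFD in controls the dedifferentiation list had 2 of 16 higher and 1 lower (camera adjusted p = 0.477), senescence genes 4 of 19 higher and 2 lower (0.574), insulin and IGF signalling 2 of 31 higher and 2 lower (0.0829), fatty acid oxidation 2 of 32 higher and 1 lower (0.805), and alpha cell markers 2 of 14 higher and 1 lower with a median of 0.67 (0.119). G2 and M phase genes had 0 of 33 passing, with a median of 0.07 against a lower camera direction (0.805), and ribosome genes 0 of 59, with a median of 0.07 against a lower camera direction (0.627). With Ctrl HFD replicates 1 and 2 left out, camera called the ribosome list lower (adjusted p = 1.65e-20, score difference −0.57 in place of −0.04) and alpha cell markers higher (0.0132, score difference 0.75 in place of 0.43).

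Of the 13 mitochondrially encoded protein genes 6 had almost no counts over all 18 libraries, mt-Co2 with 89, mt-Co3 with 58, mt-Atp6 with 38, mt-Nd4l with 21, mt-Nd3 with 16 and mt-Atp8 with 8, while mt-Co1 had 6337140. Of 44 exact permutation tests of library measures between groups, the smallest adjusted p was 0.140.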
